A study of Homo sapiens with 6 samples.

How the data were processed

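RNA was sequenced from human monocyte-derived macrophages in 6 libraries. Per the labels' protocols, monocytes were taken from blood of healthy donors with beads against CD14, seeded at 500000 cells per well and cultured for 5 days with macrophage colony-stimulating factor (M-CSF, 50 ng/ml). The macrophages were then kept for 24 h in M-CSF medium, or stimulated with interleukin-4 (IL-4, 20 ng/ml) or squalene (1 mM). The group that the labels abbreviate was read as squalene from the series title and the treatment protocol. The labels do not say whether IL-4 was also present in the squalene wells, and they name no vehicle control for squalene. Each of the 3 groups held 2 libraries, and 2 donor codes recurred in every group; the donors are called donor 1 and donor 2 here.

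The deposited table held log2-scale expression values per gene and library, made by the authors. Per the submitters' processing notes, STAR 2.7.9a, Subread 2.0.3 and featureCounts were used with the hg38 build; the order of the steps, the annotation release and the tool that made the log2 values are not given in the sources used here. The values ran from -2.29 to 19.72, and their spread between libraries shrank at low levels, which is the pattern a regularized log transformation gives. Such a transformation would understate fold changes of weakly expressed genes. The spread was smallest at levels that the filter below removed (median SD 0.004 at means of -3 to -2, against 0.31 at 2 to 4). Library medians over tested genes lay between 8.74 and 8.78, so the libraries had been scaled to each other before deposit. Whole reads could not be recovered from these values, so the sequencing depth of each library is unknown and no counting interval was computed. Of 60605 rows, 20014 (33.0%) had no gene name and carried 0.28% of the summed linear signal in the median library; they were left out of the tests. Of all rows, 22997 were at 0 in all 6 libraries, and 13217 of these had a name.

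The analysis plan had assumed linear values with a pseudocount of 1 added before taking logarithms. Because the values were already on the log2 scale they were tested as deposited, and the planned transformation was run as an alternative. Genes were kept when their mean linear value (2 to the power of the deposited value) over the 6 libraries was at least 10. Rows that shared a gene name (22) and rows from the Y chromosome or the X-inactivation centre (35) were left out, which gave 13388 tested genes. Differences were tested with limma 3.58.1 in R 4.3.3 (group means over all 6 libraries, moderated with a mean-variance trend, two-sided), and Benjamini-Hochberg adjustment within each comparison; an adjusted p under 0.05 counted as a call. The 3 comparisons were IL-4 against media, squalene against media and squalene against IL-4. Adjusted p-values below come from this limma fit unless another fit is named. The value after ± on a log2 difference is the SE of this fit, also where the adjusted p of another fit stands beside it. This SE includes the difference between donors, which cancels from differences within a donor. Only the part on other observations gives the SE of the fit named there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the figures. Gene positions were taken from GENCODE release 29, which uses the hg38 build, by gene name.

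The donor codes pair libraries across groups, and the data bore this out. Deviations from the group means of libraries with the same donor code correlated at 0.56 (media and IL-4), 0.78 (media and squalene) and 0.55 (IL-4 and squalene), across genes, which are not independent replicates. A fit with the donor as a block was planned as an alternative, and its value is given beside a result where it changed the call. With 2 donors, p-values describe these donors' wells, and 1 well per donor and treatment leaves the spread between wells unmeasured.

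Before the data were examined, 24 gene lists were fixed. They covered the IL-4 response, TREM2 lipid-associated macrophages, sterol synthesis and uptake, LXR targets, PPAR targets and fatty acid oxidation, NRF2 oxidative stress, inflammatory cytokines and NF-kB, interferon-stimulated genes, integrated stress and unfolded protein genes, matrix metalloproteinases and inhibitors, NADPH oxidase and antioxidant enzymes, the lysosome, MHC class II, the cell cycle, monocyte genes, and tissue macrophage scavenger and complement genes. Marker lists for T cells, B cells, NK cells, platelets, neutrophils, dendritic cells, erythroid cells and fibroblasts described cell types that a CD14 selection could carry over. The 17 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and the rotation test fry were alternatives. The other 7 lists had too few tested genes for a set test. Some genes are on more than 1 list.

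Genes were named by a rule fixed before the data were examined: per comparison the 10 largest rises and the 10 largest falls among calls with a mean linear value of at least 50 in the higher group and the same direction in both donors, filled up with the genes of lowest p where fewer than 5 qualified; up to 4 members per list with the lowest p; and a fixed set of genes in every comparison (among them TREM2, APOE, SPP1, GPNMB, CCL17, CD209, MRC1, SQLE, ABCA1, PLIN2, IL1B, MMP9 and HMOX1). Genes of the Y chromosome or the X-inactivation centre were never named. Genes named outside this rule are said to have been chosen after their values were seen.

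Alternatives tried were pseudocounts of 0.5, 1 and 5, no expression filter, a mean of at least 50, rescaling by the median of ratios, quantile normalization, the donor block, limma without the trend, a fit of only the 4 libraries compared, and leaving out each library in turn, where the group left with 1 library takes the spread of the others. A donor block fitted to only the 4 libraries compared was added after seeing the data.

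The fits were tested on simulated data with 200 changed genes among the 13388, in 5 simulations per comparison. Noise was drawn independently per gene with the spread of the donor block over 6 libraries, so genes did not shift together in a well. For squalene against media, the fit without a block recovered 38.8% of genes changed by 1 on the log2 scale and 72.4% of those changed by 2, and 0% of its calls were false. The donor block recovered 87.8% and 99.4% with 8.7% false calls, and the block on 4 libraries recovered 89.0% and 99.7% with 14.9% false calls, so the blocked fits exceeded the nominal rate of false calls. For IL-4 against media the corresponding shares of false calls were 0.2%, 10.8% and 20.0%, and for squalene against IL-4 they were 0.2%, 10.1% and 19.8%.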

Results

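Expression was measured by bulk RNA sequencing in human monocyte-derived macrophages from 2 donors. Each donor gave 1 library after 24 h in M-CSF medium, 1 after 24 h with IL-4 and 1 after 24 h with squalene, the hydrocarbon from which cells make sterols. The deposited values are log2 expression per gene, and their depth is unknown. Mitochondrially encoded genes took 6.4% to 7.4% of the summed linear values of a library, and the 10 most abundant genes took 13.2% to 14.7%. The first principal component (63.5% of the variance) separated the IL-4 libraries, at 45.49 and 50.03, from the other 4, which lay between -31.82 and -17.57. The second (25%) separated donor 1, at 19.32 to 23.94, from donor 2, at -24.37 to -16.61.

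The first comparison asked which transcripts differed between macrophages given IL-4 and macrophages kept in medium. ALOX15, the gene of 15-lipoxygenase on chromosome 17 (4630902 to 4642294, minus strand, hg38), rose from 7.98 ± 0.01 to 15.37 ± 0.62 (log2 value, mean ± SD, n = 2), a log2 fold change of 7.39 ± 0.28 (SE; limma, adjusted p = 0.0012). The chemokine genes CCL26 (5.77 ± 0.40), CCL17 (4.97 ± 0.16) and CCL18 (3.45 ± 0.09) rose with it. So did CD1E (5.41 ± 0.23), CD1B (4.97 ± 0.26), whose product presents lipid antigens, and the C-type lectin genes CLEC10A (4.61 ± 0.17) and CD209 (2.46 ± 0.14). CLDN1 (4.78 ± 0.96), ADAM19 (4.57 ± 0.57), DNASE1L3 (6.16 ± 1.04) and the elastase gene MMP12 (6.28 ± 1.19) also rose, with IL-4 libraries further apart between donors (SD 1.24 to 2.60). The largest falls were in the neutrophil chemokine gene CXCL5 (-4.57 ± 0.88, adjusted p = 0.040), PID1 (-4.17 ± 0.42), the 5-lipoxygenase gene ALOX5 (-3.95 ± 0.42), CD300E (-3.84 ± 0.56), LGI2 (-3.58 ± 0.61), CACNA2D3 (-3.48 ± 0.14), GAPT (-3.47 ± 0.20) and the Notch ligand gene DLL1 (-3.46 ± 0.40). The metallothionein genes MT1M (-4.19 ± 0.76) and MT1L (-4.04 ± 0.59) fell as well, although near-identical copies in that family can share reads, so the individual values are uncertain.

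By limma with Benjamini-Hochberg adjustment, 1247 of the 13388 genes passed, 646 higher and 601 lower with IL-4, of which 325 rose and 278 fell at least 2-fold. With the donor as a block 4107 passed (1994 higher, 2113 lower), and these included all 1247. The count without a block fell to 219 without media library 1, 78 without media library 2, 292 without IL-4 library 2, and 532 and 525 without squalene libraries 1 and 2. Of 57 named calls, 12 passed whichever library was left out: ALOX15, CACNA2D3, CCL17, CCL18, CCL26, CD1B, CD1E, CD209, CLEC10A, GAPT, S100A8 and VSIG4.

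**Figure D1:**
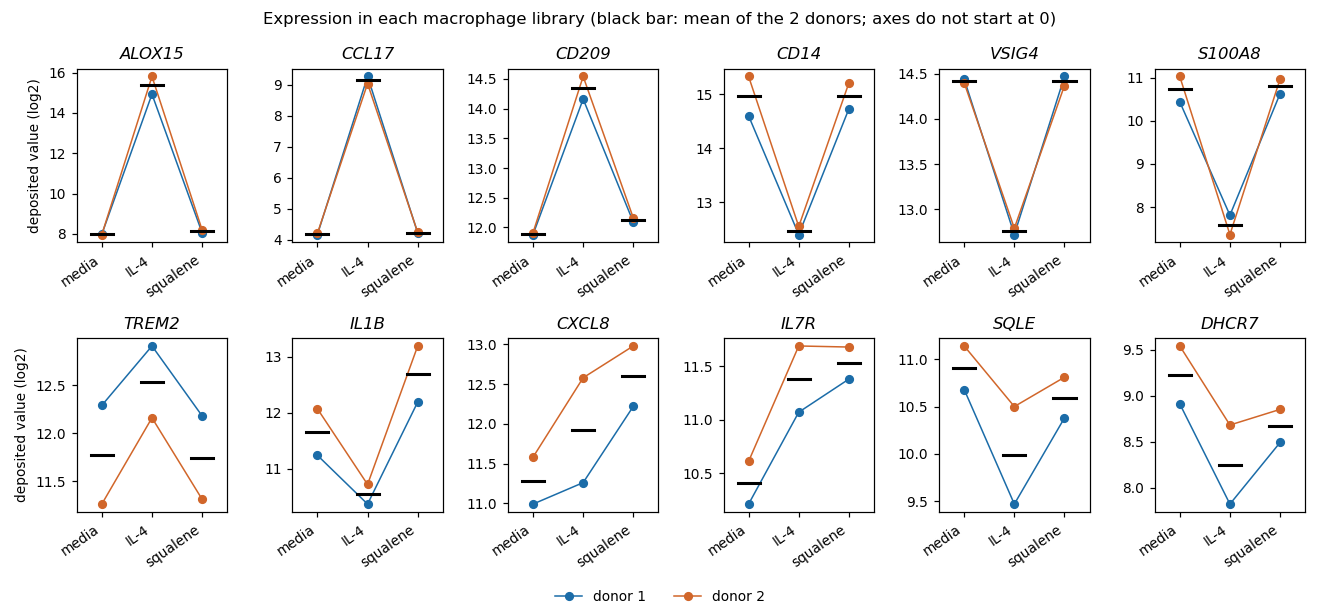
Each panel plots the deposited log2 value of a gene (vertical axis) in the media, IL-4 and squalene libraries; points are single libraries, lines join the libraries of a donor and black bars are the means of the 2 donors. ALOX15 lay at 14.93 and 15.81 with IL-4 and between 7.97 and 8.20 in the other 4 libraries, whereas IL1B was highest with squalene in each donor, at 12.19 and 13.19.

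Of the 40 genes on the IL-4 response list, 29 rose and 0 fell (36 rose when adjusted over the list alone, 37 with the donor block), with a median log2 fold change of 2.64. The camera test gave an adjusted p of 4.2e-26, an adjusted p = 0.018 with an estimated correlation, and an adjusted p = 0.11 with an estimated correlation and the donor block. The mannose receptor gene MRC1, another list member, had 0.45 ± 0.16 (adjusted p = 0.13; 0.025 with the block). In the MHC class II list 4 of 10 genes rose: the transactivator gene CIITA (1.87 ± 0.32), HLA-DMA (1.21 ± 0.20), HLA-DMB (1.00 ± 0.15) and HLA-DRB1 (1.50 ± 0.30), the last being uncertain because its reads can be shared with its paralogs. Adjusted over the list alone 8 rose, and all 10 with the block. The median was 1.65, with a camera adjusted p of 2e-05 and an adjusted p = 0.74 with an estimated correlation.

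Monocyte genes went down. Of 11 measured, 8 fell (10 adjusted over the list alone, 11 with the block), among them the calprotectin gene S100A8 (-3.15 ± 0.26), the lipopolysaccharide co-receptor gene CD14 (-2.49 ± 0.28), the ficolin gene FCN1 (-1.51 ± 0.19) and MNDA (-0.65 ± 0.07). The median was -1.51 (camera adjusted p = 4.3e-08; adjusted p = 0.19 with an estimated correlation). Among 16 tissue macrophage scavenger and complement genes, 5 fell and 1 rose (10 and 1 adjusted over the list alone, 11 and 1 with the block). SELENOP (-2.04 ± 0.23), the complement receptor gene VSIG4 (-1.66 ± 0.09), the haemoglobin scavenger receptor gene CD163 (-1.31 ± 0.16) and the scavenger receptor gene MSR1 (-0.65 ± 0.10) fell, whereas the complement gene C1QB rose (1.73 ± 0.20). The median was -0.96 (camera adjusted p = 1.2e-04; adjusted p = 0.19 with an estimated correlation). HERC5 (-1.80 ± 0.26) and IFI44 (-0.99 ± 0.18) fell among 25 interferon-stimulated genes, for which 6 fell adjusted over the list alone and 19 with the block, with a median of -0.91 (camera adjusted p = 1.4e-06; adjusted p = 0.74 with an estimated correlation).

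The cell cycle list had a median of -1.53 (camera adjusted p = 5.1e-06; adjusted p = 0.84 with an estimated correlation), but none of its 18 genes passed over all genes; 13 fell adjusted over the list alone and 16 with the block. TOP2A was -2.31 ± 0.54 (adjusted p = 0.060; 0.0054 with the block), and media libraries differed between donors for this gene (SD 0.98). The sterol synthesis and uptake list had a median of -0.30 (camera adjusted p = 0.013; adjusted p = 0.97 with an estimated correlation, 0.21 without media library 2 and 0.81 without IL-4 library 1). Of its 24 genes the lanosterol synthase gene LSS fell (-0.44 ± 0.09) and INSIG1, whose product retains the sterol-sensing SREBP complex in the endoplasmic reticulum, rose (0.81 ± 0.17). Adjusted over the list alone 0 passed, and with the block 1 rose and 8 fell. SQLE, the squalene epoxidase gene, was -0.92 ± 0.37 (adjusted p = 0.17; 0.0099 with the block) and DHCR7 was -0.98 ± 0.35 (0.14; 0.0051).

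Members of the remaining lists went in both directions. In the TREM2 lipid-associated macrophage list 2 of 26 genes fell, NUPR1 (-2.27 ± 0.20) and MSR1. 2 also fell adjusted over the list alone, while 8 rose and 10 fell with the block, and the median was -0.07 (camera adjusted p = 0.64). Within donors the medians were -0.10 and -0.05, and the direction of the list test depended on the library left out. TREM2 itself (chromosome 6, 41158506 to 41163186, minus strand) was 12.54 ± 0.52 with IL-4 and 11.77 ± 0.73 in media, a difference of 0.76 ± 0.47 that passed only with the block (adjusted p = 0.34 without it, 0.0026 with it). SPP1 (-1.61 ± 0.39; 0.064 and 0.0013), APOE (-0.57 ± 1.04; 0.76 and 0.0040) and GPNMB (-0.39 ± 0.26; 0.38 and 0.012) passed on the lower side with the block alone. PLIN2 (-0.08 ± 0.64; 0.95 and 0.83) passed neither fit. Of 15 LXR targets PLTP (-1.02 ± 0.21) and SMPDL3A (-0.86 ± 0.18) fell (1 rose and 4 fell adjusted over the list alone; 3 rose and 6 fell with the block). The list's median of 0.03 differed in sign from its mean of -0.22 and its test, which was not called (camera adjusted p = 0.64). ABCA1 was -0.71 ± 0.20 (adjusted p = 0.090; 0.011 with the block). No PPAR or fatty acid oxidation gene passed of 20, also adjusted over the list alone. With the block 10 rose and 1 fell, which also moved the camera adjusted p from 0.055 to 0.0017 (median 0.32; adjusted p = 0.23 with an estimated correlation and the block). Without media library 1 or IL-4 library 2 it was 0.0030 or 9.2e-04, and 0.044 without either squalene library. The receptor gene PPARG was 1.25 ± 0.43 (adjusted p = 0.13; 0.0022 with the block).

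Among 18 NRF2 genes OSGIN1 (1.01 ± 0.10), SRXN1 (1.25 ± 0.25) and the cystine transporter gene SLC7A11 (1.85 ± 0.37) rose and AKR1B1 fell (-0.78 ± 0.09). 5 rose and 3 fell adjusted over the list alone, and 6 and 4 with the block (median 0.14, camera adjusted p = 0.42). HMOX1, the haem oxygenase gene, was -0.21 ± 0.31 (adjusted p = 0.71). Inflammatory genes split: 4 of 21 rose, including TRAF1 (2.72 ± 0.50), CCL3 (1.71 ± 0.31) and ICAM1 (1.34 ± 0.23). CXCL5 fell (6 and 4 adjusted over the list alone, 7 and 5 with the block; median 0.08, camera adjusted p = 0.64, and 0.043 without IL-4 library 1). IL1B was -1.11 ± 0.41 (adjusted p = 0.15; 0.0056 with the block). Of the matrix metalloproteinase list MMP12 and MMP1 (2.15 ± 0.32) rose and the gelatinase gene MMP2 fell (-2.22 ± 0.30), the same numbers adjusted over the list alone, with a median of -0.25, a mean of 0.28 and a camera adjusted p of 0.75. 2 rose and 5 fell with the block. MMP9 was -0.53 ± 0.23 (0.20; 0.049). Among 15 NADPH oxidase and antioxidant genes the thioredoxin gene TXN rose (0.88 ± 0.17), and CYBB (-1.64 ± 0.14), NCF4 (-0.67 ± 0.12) and NCF1 (-1.44 ± 0.29, uncertain because pseudogenes share its reads), which encode subunits of the oxidase, fell. 1 rose and 3 fell adjusted over the list alone, and 6 and 4 with the block (median 0.05, mean -0.09, camera adjusted p = 0.97). SLC7A11 and SHMT2 (0.44 ± 0.07) rose among 16 integrated stress and unfolded protein genes, 2 also adjusted over the list alone and 5 with the block, where 3 fell (median -0.08, mean 0.16, camera adjusted p = 0.95). No lysosome gene passed of 22 or adjusted over the list alone. 7 rose and 3 fell with the block (median 0.03, camera adjusted p = 0.64).

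Markers of other blood cells were low or did not move together. No T cell marker passed of 9, also adjusted over the list alone (median -0.10, camera adjusted p = 0.77). With the block IL7R was higher (0.97 ± 0.25, adjusted p = 0.0016) and CD28 lower (-0.90 ± 0.26, adjusted p = 0.0062), and both genes were already expressed in media, at 10.41 and 11.70. The B cell, NK cell, neutrophil and fibroblast lists had 3, 3, 3 and 1 tested genes, of which none passed, and no erythroid gene was high enough to be tested. With the block, 1 neutrophil marker, MME, was higher (1.08 ± 0.70, adjusted p = 0.019). The dendritic cell marker XCR1 fell (-1.86 ± 0.33), while LAMP3 (2.73 ± 0.66, adjusted p = 0.063) passed with the block (0.0072). Of 2 platelet markers PPBP was -3.51 ± 0.85 (adjusted p = 0.062; 0.0013 with the block, and 1 marker lower adjusted over the list alone) and TUBB1 was 0.57 ± 0.28 (0.24).

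The second comparison asked which transcripts differed between macrophages given squalene and macrophages kept in medium. Inflammatory cytokine transcripts were higher in both donors, but no single gene passed the planned test. IL1B, the interleukin-1β gene on chromosome 2 (112829751 to 112836903, minus strand), had 12.69 ± 0.71 with squalene and 11.65 ± 0.59 in media, a difference of 1.04 ± 0.41, or 0.95 in donor 1 and 1.13 in donor 2. IL1A (1.66 ± 0.21), the neutrophil chemokine gene CXCL8 (1.31 ± 0.50) and IL6 (1.02 ± 0.39) lay above media in both donors too. So did the monocyte chemokine gene CCL13 (1.37 ± 0.32), the interleukin-7 receptor gene IL7R (1.12 ± 0.25), HSD11B1 (0.91 ± 0.18), the immediate early gene EGR1 (0.89 ± 0.17) and SERPINB2 (0.82 ± 0.10). On the lower side the differences were smaller: GLUD1P3 (-0.61 ± 0.19, a pseudogene whose reads may belong to its parent gene), FAXDC2 (-0.57 ± 0.17), the thiolase gene ACAT2 (-0.49 ± 0.15), CALCRL (-0.46 ± 0.16) and ZC3H12D (-0.38 ± 0.09). All of these had an adjusted p of 1.

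By limma 0 of the 13388 genes passed without a block. In that fit 151 had an unadjusted p under 0.05, where 669 would by chance. Its spread includes the difference between donors, which cancels from the fold changes (median SE 0.151 against 0.105 with the block). The 151 therefore do not show that squalene had no effect. With the donor block over all 6 libraries 0 passed (663 unadjusted, lowest adjusted p 0.21, SERPINB2 and IL7R). Leaving out any library gave 0 as well. A donor block fitted to only the 4 media and squalene libraries, chosen after seeing the data, called 360 genes, 259 higher and 101 lower (29 higher and 0 lower at least 2-fold; 1990 unadjusted). The median SE was 0.084 in this fit against 0.105 with the block over 6 libraries, and the moderated degrees of freedom were 14.05 against 5.68. What made the counts differ was not tested. The 4-library blocked fit rests on 1 residual degree of freedom moderated across genes. Its share of false calls on simulated data was 14.9%, but the simulated noise was independent per gene with the spread of the block over 6 libraries. Shifts of many genes together in a well were not simulated, so 14.9% does not measure the false share of the 360 calls. The adjusted p in this fit was 1.2e-08 for CXCL8, 8.4e-08 for IL1B, 2.9e-08 for CCL13, 4.9e-08 for IL7R, 1.6e-04 for IL1A and 0.0016 for IL6.

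All 21 inflammatory cytokine and NF-kB genes measured lay above media, with a median log2 difference of 0.65 (0.70 in donor 1, 0.55 in donor 2). The camera adjusted p was 3.3e-13, and the adjusted p was 0.40 with an estimated correlation. None passed over all genes, 1 did adjusted over the list alone, 15 did adjusted over the list alone with the donor block, and 17 did in the 4-library blocked fit, among them PTGS2, the inducible cyclooxygenase gene (0.67, adjusted p = 1.6e-04), CCL3 (0.57, 0.0045), ICAM1 (0.50, 9.9e-05) and SOD2 (0.42, 0.0055). PTGS2, CCL3 and ICAM1 were chosen here after their values were seen. The camera call held whichever library was left out. Interferon-stimulated genes did not move with them: of 25, 0 passed in any of these fits, also adjusted over the list alone, the median was 0.02, and CXCL11 (0.55 ± 0.34), IFI27 (0.31 ± 0.29), GBP1 (0.24 ± 0.17) and GBP4 (-0.23 ± 0.24) went both ways (camera adjusted p = 0.67). Leaving out a media or squalene library turned that test either way, up without media library 1 (adjusted p = 5.2e-05) or squalene library 2 (1.5e-06) and down without media library 2 (0.0027) or squalene library 1 (0.014). Each of these sets 2 donors against 1, and within donors the list's medians were 0.03 and 0.01.

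Sterol genes were lower. Of 24 sterol synthesis and uptake genes 22 lay below media, with a median of -0.21 (camera adjusted p = 6.6e-06; adjusted p = 0.84 with an estimated correlation, 0.15 without media library 2). None passed over all genes or adjusted over the list alone, with or without the block over 6 libraries. 7 were lower in the 4-library blocked fit. SQLE (chromosome 8, 124998497 to 125022283, plus strand) had 10.60 ± 0.31 with squalene and 10.91 ± 0.33 in media, a difference of -0.31 ± 0.37 (adjusted p = 0.0084 in the 4-library blocked fit). DHCR7, the gene of the last step to cholesterol, differed by -0.55 ± 0.35 (0.0025). FDFT1, the squalene synthase gene, was -0.34 ± 0.26. Among 15 LXR targets the sterol exporter gene ABCA1 (0.30 ± 0.20; 0.0072 in the 4-library blocked fit) and the receptor gene NR1H3 (0.46 ± 0.23; 2.8e-04) lay above media and SCD (-0.12 ± 0.12) below. 0 passed over all genes or adjusted over the list alone, 1 did adjusted over the list alone with the block, and 3 were higher and 1 lower in the 4-library blocked fit (median 0.02, camera adjusted p = 0.54).

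The IL-4 response list lay slightly above media, with a median of 0.16 and 31 of 40 genes above 0 (camera adjusted p = 2.5e-05; adjusted p = 0.21 with an estimated correlation). None passed over all genes or adjusted over the list alone, 9 were higher adjusted over the list alone with the block, and 12 were higher and 1 lower in the 4-library blocked fit. The examples were CCL13, the cytokine signalling inhibitor gene CISH (0.56 ± 0.18), CCL18 (0.53 ± 0.09) and the cathepsin gene CTSC (0.36 ± 0.12). The 10 genes with the largest IL-4 rises were looked at here after their values were seen. Of these, CLDN1 (1.28 ± 0.96, adjusted p = 0.017) and CLEC10A (0.38 ± 0.17, 0.022) were higher in the 4-library blocked fit. MMP12 (0.52 ± 1.19), CD1B (0.36 ± 0.26), ADAM19 (0.21 ± 0.57), ALOX15 (0.15 ± 0.28), CD1E (0.14 ± 0.23), DNASE1L3 (0.09 ± 1.04), CCL26 (0.05 ± 0.40) and CCL17 (0.04 ± 0.16) did not pass in any of these fits. CD209 (0.23 ± 0.14, adjusted p = 0.026) and MRC1 (0.43 ± 0.16, 0.0062) were higher in the 4-library blocked fit.

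Integrated stress and unfolded protein genes had a median of 0.19, with 15 of 16 above media, among them SLC7A11 (1.05 ± 0.37), the chaperone gene HSPA5 (0.25 ± 0.14), DNAJB9 (0.24 ± 0.10) and SDF2L1 (0.24 ± 0.14) (camera adjusted p = 1.8e-04; adjusted p = 0.40 with an estimated correlation; 3 higher in the 4-library blocked fit). Matrix metalloproteinases and inhibitors had a median of 0.17 (camera adjusted p = 0.049; 0.054 with the block, and adjusted p = 0.40 with an estimated correlation), with MMP8 (1.26 ± 0.87), MMP1 (1.08 ± 0.32), MMP14 (0.33 ± 0.11), MMP9 (0.27 ± 0.23) and TIMP1 (0.15 ± 0.08) above media. The call was lost without media library 1 (0.058), media library 2 (0.13), IL-4 library 1 (0.051), IL-4 library 2 (0.050) or squalene library 1 (0.24), and 3 were higher and 1 lower in the 4-library blocked fit. All 18 cell cycle genes lay below media, with a median of -0.23 (camera adjusted p = 0.0077; adjusted p = 0.95 with an estimated correlation), for example CENPF (-0.51 ± 0.55) and TOP2A (-0.44 ± 0.54), and 4 were lower in the 4-library blocked fit. The test was called in the opposite direction without media library 2 (0.0051) and was lost without squalene library 1 (0.24). Leaving out a library sets 2 donors against 1, and within donors the list's medians were -0.16 and -0.30. In these 3 lists 0 genes passed over all genes or adjusted over the list alone. With the block 3 metalloproteinase list genes were higher and 1 lower adjusted over the list alone.

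TREM2 and the genes of lipid-associated macrophages had no member past the planned test. TREM2 had 11.75 ± 0.62 with squalene and 11.77 ± 0.73 in media, a difference of -0.02 ± 0.47 (95% interval -1.20 to 1.15, or -0.23 to 0.18 with the block), -0.10 in donor 1 and 0.05 in donor 2. SPP1 (0.03 ± 0.39), APOE (0.01 ± 1.04), PLIN2 (0.03 ± 0.64), GPNMB (-0.18 ± 0.26), CD9 (-0.25 ± 0.17), CTSL (0.45 ± 0.34) and NUPR1 (-0.50 ± 0.20) had no common direction. These SEs include the difference between donors. In donors 1 and 2, SPP1 differed by 0.03 and 0.04, APOE by -0.07 and 0.08 and PLIN2 by -0.06 and 0.12. GPNMB differed by -0.18 and -0.19, CD9 by -0.26 and -0.23, CTSL by 0.30 and 0.60 and NUPR1 by -0.22 and -0.78. Of the 26 genes on the list 0 passed over all genes or adjusted over the list alone, with or without the block over 6 libraries. In the 4-library blocked fit 1 was higher, CTSL (adjusted p = 0.0025), and 1 lower, CD9 (0.019), or 2 and 7 adjusted over the list alone. The median was 0.01, the mean -0.02 and the camera adjusted p 0.67, on the lower side. Without media library 1 (0.0013) or squalene library 2 (0.0085) the list tested as higher, and without media library 2 (9.9e-05) or squalene library 1 (0.014) as lower, while its medians within donors were -0.06 and 0.05.

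**Figure D2:**
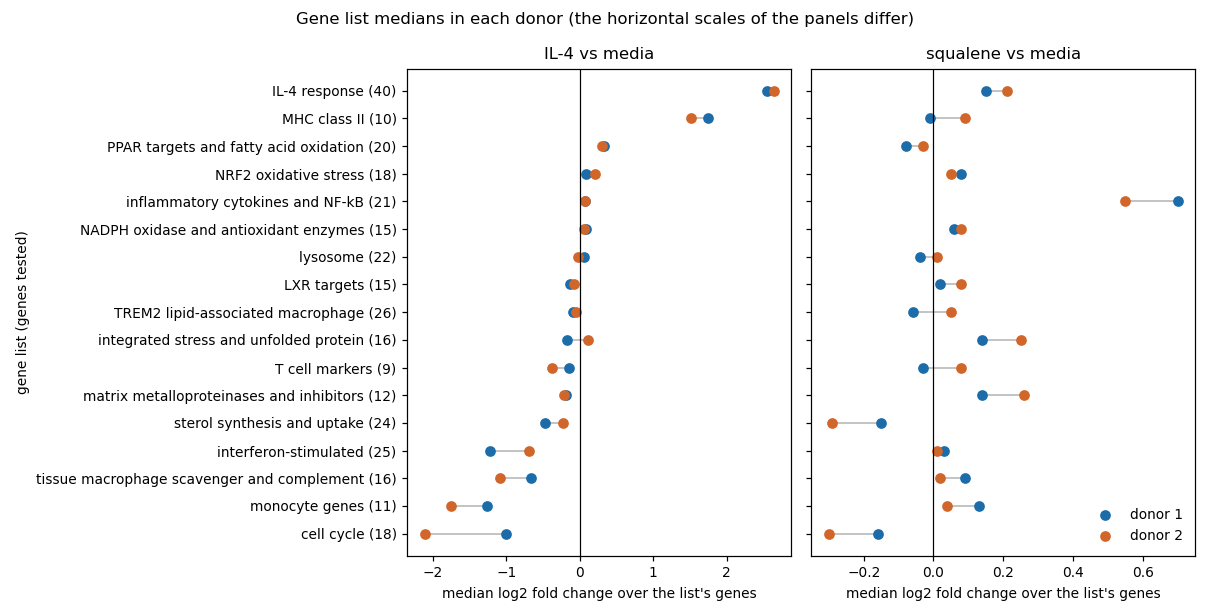
Points are the median log2 fold change over the tested genes of each list (vertical axis, number of genes in brackets) in donor 1 and donor 2, for IL-4 against media and for squalene against media, with different horizontal scales. The inflammatory list stood at 0.70 and 0.55 with squalene and at 0.07 in both donors with IL-4, and the IL-4 response list at 2.55 and 2.64 with IL-4.

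In the other lists 0 genes passed with squalene over all genes, with or without the block over 6 libraries. In the 4-library blocked fit 3 monocyte genes were higher, 2 PPAR and fatty acid oxidation genes lower, 2 NADPH oxidase and antioxidant genes higher, and 1 scavenger and complement gene, 1 T cell marker and 1 platelet marker higher. In that fit 2 lysosome genes were higher and 1 lower, 1 NRF2 gene was higher and 1 lower, and 0 MHC class II genes passed. PPAR and fatty acid oxidation genes had a median of -0.03 and a camera adjusted p of 0.44, which became 0.045 on the lower side with the block (adjusted p = 0.51 with an estimated correlation and the block), 0.0017 without media library 2 and 0.033 without squalene library 1. CPT1A was -0.29 ± 0.31 (adjusted p = 0.013 in the 4-library blocked fit). NRF2 genes had a median of 0.06 (camera adjusted p = 0.32; higher without media library 1, 3.7e-04, and squalene library 2, 1.1e-05), with HMOX1 at -0.30 ± 0.31 (0.0055 in the 4-library blocked fit) and GCLM at 0.17 ± 0.10. NADPH oxidase and antioxidant genes had 0.06 (0.27; 0.021 without squalene library 2), lysosome genes -0.02 (0.83; 0.036 on the lower side without media library 2 and 0.040 on the higher without squalene library 2), and scavenger and complement genes 0.08 (0.66), with CYBB at 0.19 ± 0.14, NPC1 at 0.26 ± 0.22 (0.012 in the 4-library blocked fit) and SELENOP at -0.41 ± 0.23. For MHC class II genes the median was 0.01 and the mean 0.03 while the test pointed down (0.71; lower without media library 1, 0.0028, and squalene library 2, 3.7e-04, and higher without media library 2, 0.016). Monocyte genes had a median of 0.15 (0.29), or 0.13 and 0.04 within donors. Without media library 2, which sets 2 donors against 1, the list was called higher (1.9e-04), and without media library 1 it pointed down (0.16). CD14 (0.01 ± 0.28), S100A8 (0.06 ± 0.26) and FCN1 (-0.10 ± 0.19), chosen here after their values were seen, did not pass in any of these fits. VCAN (0.49 ± 0.43, adjusted p = 0.0037) and CD300E (0.78 ± 0.56, 4.6e-06) were higher in the 4-library blocked fit, where their SE was 0.08 and 0.06. T cell markers had a median of -0.03, a mean of 0.09 and a camera adjusted p of 0.71 on the higher side (0.041 without media library 2). 1 of them, IL7R, passed adjusted over the list alone. B cell, NK cell, neutrophil, dendritic cell and fibroblast markers had medians of -0.16, -0.20, -0.32, 0.01 (mean -0.02) and -0.38 with 0 genes past the test. Of the platelet markers PPBP was 1.31 ± 0.85 and TUBB1 -0.06 ± 0.28, with 1 higher adjusted over the list alone with the block.

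The third comparison tested the difference between the stimuli directly. Squalene libraries lay far below IL-4 libraries in ALOX15 (-7.24 ± 0.28, adjusted p = 0.0012), DNASE1L3 (-6.06 ± 1.04), CCL26 (-5.73 ± 0.40), CD1E (-5.28 ± 0.23), CCL17 (-4.93 ± 0.16), CD1B (-4.61 ± 0.26), GALNT18 (-4.37 ± 0.28), ADAM19 (-4.36 ± 0.57), PPP1R14A (-4.36 ± 0.28) and the forkhead factor gene FOXQ1 (-4.30 ± 0.29). They lay far above them in CXCL5 (5.64 ± 0.88), the platelet basic protein gene PPBP (4.82 ± 0.85), CD300E (4.62 ± 0.56), PID1 (4.39 ± 0.42), ALOX5 (4.17 ± 0.42), the versican gene VCAN (3.83 ± 0.43), DLL1 (3.63 ± 0.40), SERPINB2 (3.62 ± 0.10) and LGI2 (3.62 ± 0.61). By limma 948 genes passed, 513 higher and 435 lower with squalene, and 3445 with the donor block (1862 and 1583), including all 948. Of the 1247 genes that IL-4 changed against media, 850 differed here; both comparisons use the same IL-4 libraries. The count fell to 528 and 527 without media libraries 1 and 2, 245 without IL-4 library 2, and 77 and 73 without squalene libraries 1 and 2. Leaving out any library, 13 of 51 named calls still passed, including ALOX15, CCL17, CCL18, CCL26, FOXQ1, SERPINB2 and VSIG4.

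By list, 26 of 40 IL-4 response genes were lower with squalene (35 adjusted over the list alone; 36 lower and 1 higher with the block; median -2.37, camera adjusted p = 1.3e-26, adjusted p = 0.017 with an estimated correlation and 0.11 with an estimated correlation and the block). MHC class II genes were lower, 3 of 10 (8 adjusted over the list alone, 10 with the block): CIITA (-1.89 ± 0.32), HLA-DMA (-1.22 ± 0.20) and HLA-DMB (-1.20 ± 0.15), with a median of -1.53 (7.3e-06; adjusted p = 0.68 with an estimated correlation). Monocyte genes were higher, 8 of 11 (10 adjusted over the list alone, 11 with the block; median 1.68, camera adjusted p = 5e-09, adjusted p = 0.16 with an estimated correlation). Of scavenger and complement genes 5 were higher and 1 lower (10 and 1 adjusted over the list alone, 12 and 1 with the block; median 0.93, 3.7e-05, adjusted p = 0.16 with an estimated correlation). HERC5 (1.70 ± 0.26) and IFI44 (1.07 ± 0.18) were higher among interferon-stimulated genes (11 adjusted over the list alone, 20 with the block; median 0.96, 1.6e-07, adjusted p = 0.68 with an estimated correlation). No cell cycle gene passed, also adjusted over the list alone, against 14 higher with the block (median 1.23, 6e-05, adjusted p = 0.81 with an estimated correlation). No PPAR gene passed in either count, against 1 higher and 11 lower with the block. The median was -0.47 (0.016, adjusted p = 0.81 with an estimated correlation; 0.20 without IL-4 library 1 and 0.17 without squalene library 2).

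Inflammatory genes were higher in 5 of 21, among them CXCL5, IL1B (2.14 ± 0.41), PTGS2 (1.97 ± 0.35) and IL1A (1.58 ± 0.21). 6 were higher and 3 lower adjusted over the list alone, and 12 and 5 with the block. The list's median was 0.82, with a camera adjusted p of 0.21, or 0.022 with the block (adjusted p = 0.30 with an estimated correlation and the block), 0.014 without IL-4 library 2 and 0.049 without squalene library 1. The LXR targets ABCA1 (1.01 ± 0.20) and SMPDL3A (1.17 ± 0.18) were higher (4 adjusted over the list alone; 6 higher and 2 lower with the block; median 0.09, 0.48). In the TREM2 list NUPR1 (1.77 ± 0.20) and MSR1 (0.72 ± 0.10) were higher (2 adjusted over the list alone; 9 higher and 8 lower with the block; median 0.11, 0.58). TREM2 was -0.79 ± 0.47 (adjusted p = 0.36; 0.0026 with the block). INSIG1 was the 1 sterol gene that passed (-1.02 ± 0.17; 1 adjusted over the list alone, 1 higher and 1 lower with the block; median 0.10, 0.48, and 9.3e-05 without IL-4 library 2). SQLE was 0.61 ± 0.37 (0.36; 0.038 with the block).

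AKR1B1 (0.84 ± 0.09) was higher and OSGIN1 (-0.99 ± 0.10) lower among NRF2 genes (1 and 3 adjusted over the list alone, 4 and 5 with the block; median -0.08, 0.48). SDF2L1 (0.73 ± 0.14) was higher and SHMT2 (-0.38 ± 0.07) lower among stress and unfolded protein genes (4 and 1 adjusted over the list alone, 6 and 3 with the block; median 0.17, 0.48). MMP2 was higher (adjusted p = 0.024) in the metalloproteinase list (3 higher and 2 lower adjusted over the list alone, 6 and 2 with the block; median 0.34, mean 0.00, 0.37). CYBB (1.83 ± 0.14), NCF1 (1.60 ± 0.29), SOD2 (1.03 ± 0.19) and NCF4 (0.60 ± 0.12) were higher among NADPH oxidase and antioxidant genes (4 higher and 2 lower adjusted over the list alone, 4 and 5 with the block; median -0.02, mean 0.16, 0.67). No lysosome gene passed, also adjusted over the list alone (4 higher and 6 lower with the block; median -0.06, 0.48, and 0.048 without IL-4 library 2). Of the marker lists, XCR1 (1.64 ± 0.33) and PPBP passed, T cell markers had a median of 0.15 (0.50) with 1 higher with the block, and B cell, NK cell, neutrophil and fibroblast markers had medians of -0.64, 0.02, -0.25 and 0.32 with 0 past the test (1 neutrophil marker lower with the block).

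Across the 13388 genes, which are not independent replicates, the log2 fold changes of IL-4 and squalene against media had a Pearson correlation of 0.28 and a Spearman correlation of 0.32, and 62.5% of genes had the same sign. Both comparisons use the same 2 media libraries, and simulated unchanged groups against those libraries gave 0.50, 0.46 and 66.7%. The simulation left both groups unchanged, whereas IL-4 changed many genes. It therefore cannot show whether the observed values lie below or above chance. The covariance was 0.0328 against a simulated 0.0119 with the spread of the blocked fit, and against 0.0319 with the spread of the fit without a block. The spread without a block includes the difference between donors, which cancels from both fold changes because each group held the same 2 donors. The blocked spread is thus closer to the design, and against it the covariance was higher, but the spread between wells is unmeasured. With the IL-4 effect of donor 1 and the squalene effect of donor 2, which share no media library, the Pearson correlation was 0.21 (covariance 0.0333). With the donors exchanged it was 0.11 (covariance 0.0155). Because squalene had 0 calls in the fit over 6 libraries, no overlap of calls could be counted there.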

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

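In this part, tests of monocytes or other cell types and of a fixed share of exposed cells were chosen after their result was seen. The other 4 were set before the value they measure was seen, but after the pattern they address had been stated.

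Among 1138 unnamed loci high enough to test, which no comparison above used, 37 differed between IL-4 and media by limma in a fit and adjustment over named genes and unnamed loci together (15 higher, 22 lower, 3.3% against 9.1% of named genes, and 127 with the donor block). Between squalene and IL-4, 26 of these loci differed (16 higher, 10 lower, 2.3% against 7.0% of named genes, and 114 with the block).

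Inflammatory cytokine and NF-kB genes lay above media with squalene in both donors, with a median of 0.65. Undifferentiated monocytes would raise monocyte genes as well, and their median was 0.15 (SE 0.08) where the prediction set a level of 0.33, a difference of -0.18 (SE 0.10) that passes the 1 SE asked for by that prediction but not 2 SE, a bar set after the value was seen, so that monocytes are left open here, with 3 of 11 monocyte genes higher in the 4-library blocked fit, CD14, S100A8 and FCN1 at 0.01, 0.06 and -0.10, and list medians of 0.13 and 0.04 within donors; T cell, B cell, NK cell and neutrophil markers had medians of -0.03, -0.16, -0.20 and -0.32. A chance deviation of 1 media library alone would leave the other donor unmoved. The medians in the donors taken alone were 0.70 (SE 0.11) and 0.55 (SE 0.17). These SEs come from resampling the list's genes, which are not independent, so they do not measure the spread between wells. The pattern had been stated as a rise in both donors, so this test could hardly have come out otherwise. With 1 well per donor and treatment, chance shifts in the wells of both donors are not excluded. The rotation test fry gave an adjusted p of 0.59, or 0.076 with the block. A general scaling of the squalene libraries would move random lists of the same mean level alike. The list's median stood at percentile 100 of 10000 such lists. Camera, which had called the list, also sets it against other genes, so this percentile is not separate support. A response of the macrophages to squalene, monocytes left undifferentiated, chance shifts between wells, a microbial contaminant and the unnamed vehicle of squalene stay open, the last 2 untested.

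IL-4 response genes lay slightly above media with squalene, with a median of 0.16. Noise of single media libraries shared by both comparisons would give a correlation near 0 with donors crossed. The lower correlation over the genes IL-4 changed, which were called with both donors' media libraries, was 0.22. Over genes chosen by a 2-fold IL-4 change in the other donor alone it was 0.33 and 0.19. These values argue against such noise as the whole cause over those genes, which are not independent and are not the list alone. A shift common to both media wells would remain with donors crossed and is not excluded. Traces of IL-4, or cells exposed to it, in the squalene wells would raise IL-4 risers, the largest most, and lower IL-4 fallers. With donors crossed, the median squalene effect was 0.125 and 0.058 for risers and -0.065 and -0.008 for fallers. The 10 largest risers had 0.19 and 0.159, so all 3 medians went the predicted way. The 10 largest stood at percentile 81.6 and 95.4 of random draws of 10 risers, a stricter comparison than predicted. With genes chosen in 1 donor alone, the 10 largest had 0.093 and 0.159 against 0.144 and 0.061 for risers over 2-fold. Fallers over 2-fold chosen this way had -0.153 and -0.038, on the predicted side. Together these values decide neither way. A fixed share of IL-4-exposed cells fitted best at 0.825%. It left 7 of the 29 called list genes over 2 SE from the level it predicts, 6 above and 1 below (ALOX15). The 10 largest risers implied median shares of 0.183% and 0.276%, against 3.33% and 1.84% for other called list genes. Several of the 10 lay low without IL-4 (CCL26 at 2.86 to 2.94, CCL17 at 4.16 to 4.23), where the values may understate differences. ALOX15 (7.97 to 8.20) and CLEC10A (8.29 to 9.01) lay higher. The gap would argue against 1 share, but this limit and the assumed profile of the IL-4 wells leave it open. The labels do not say whether squalene wells received IL-4, but a full response to it was absent (ALOX15 at 8.13 against 15.37 with IL-4). For this list the rotation test fry gave an adjusted p of 0.30, or 0.14 with the block. Camera with an estimated correlation gave an adjusted p of 0.21. Traces of IL-4, a small share of exposed cells, a response of the cells to squalene and chance shifts between wells could not be told apart. The unnamed vehicle of squalene and a microbial contaminant were not tested.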

How the results depend on the processing

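The donor block fitted to only the 4 libraries compared was chosen after seeing the data; the other alternatives were fixed before the data were examined.

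With the donor as a replicate block the calls for IL-4 against media went from 1247 to 4107 and for squalene against IL-4 from 948 to 3445, because the block removes the difference between donors from the spread. With the block and only the 4 libraries compared they were 2790 and 2170, and squalene against media went from 0 to 360; the cause was not tested. Without a block, the fit of only the 4 libraries compared gave 527 for IL-4 against media and 527 for squalene against IL-4, no expression filter gave 637 and 503, and limma without the trend gave 806 for IL-4 against media; the cause was not tested. Leaving out a library gave 78 to 1081 for IL-4 against media, 73 to 783 for squalene against IL-4, and 0 for squalene against media. Pseudocounts of 0.5, 1 and 5 gave 1246, 1246 and 1237 for IL-4 against media, a mean of at least 50 gave 1218, the median of ratios 1238 and quantile normalization 1185. Of the named genes' values under the alternatives, 4744 were classed as the same, 193 newly passed, 434 no longer passed and 108 moved. Of the named calls, 0 reversed when a library was left out, whereas differences that were not called could change sign.

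Camera called 7 lists for IL-4 against media, 6 for squalene against media and 7 for squalene against IL-4. With an estimated correlation it called 1, 0 and 1, with an estimated correlation and the replicate block 0, 0 and 0, and fry called 3, 0 and 4; with the replicate block fry called 6, 0 and 9. Leaving out a library gave 5 to 12 lists for squalene against media. The correlation of IL-4 and squalene effects was 0.28, and 0.21 and 0.11 with donors crossed, where no media library is shared. The cause of the other differences was not tested. The planned tests on recovered reads were not run, because whole reads could not be recovered from log2 values, and the depth that limits weakly expressed genes is unknown.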

Other observations

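All genes and groups in this part, except the platelet markers, were chosen after their values were seen, and the fit they rest on for squalene was added after seeing the data.

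In the donor-blocked limma fit of the 4 media and squalene libraries, rises outside the named genes included STAC (1.97 ± 0.16, adjusted p = 9.9e-06), TNIP3 (1.32 ± 0.14, 1.2e-04), the activin subunit gene INHBA (1.29 ± 0.19, 0.0021), the monocyte chemokine gene CCL7 (1.27 ± 0.06, 1.2e-08) and the integrin gene ITGB3 (1.07 ± 0.16, 0.0025). Falls were smaller, as in the serine dehydratase gene SDS (-0.77 ± 0.10, 9.9e-04). None of these genes passed in the fits over 6 libraries. Grouped by gene symbol, 13 of 161 families with at least 10 genes passed camera over 6 libraries. The medians were 0.53 for 19 CCL genes (adjusted p = 2.2e-08) and 0.78 for 11 CXCL genes (0.013), 0.23 for CLEC, 0.14 for HSPA, 0.11 for RPL, 0.10 for CCT, 0.09 for UTP, 0.08 for MRPL and LSM, 0.07 for PSMD, 0.06 for EIF and 0.05 for UBE genes, and -0.07 for 28 mitochondrially encoded genes. With an estimated correlation and the block all 13 had an adjusted p = 0.94. The direction of these medians was not checked under other scalings.

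The 9 tested metallothionein genes, which lie on chromosome 16 and bind zinc and copper, had a median of -2.90 with IL-4, between -4.19 and -2.42, and all 9 lay below media in both donors (4 fell without a block, 8 with it). With squalene the median was -0.45, and 8 of 9 lay below media in both donors (0 passed in the fits over 6 libraries, 5 in the 4-library blocked fit). Paralogs in this family can share reads, so single members are uncertain.

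PPBP, the gene of platelet basic protein, had values of 9.33 and 10.57 in media, 5.92 and 6.96 with IL-4, and 10.12 and 12.39 with squalene. PF4, too low to be tested, lay at 2.46 and 3.43 in media, 1.60 and 1.85 with IL-4, and 2.64 and 4.33 with squalene. TUBB1 lay between 3.88 and 4.97 in all 6 libraries.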
